A study of Homo sapiens with 6 samples.

How the data were processed

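Gene expression was measured by 151-base paired-end RNA sequencing of total RNA from human aortic smooth muscle cells (HASMC), per the labels. The labels give 2 groups of 3 libraries with replicate numbers 1 to 3, BSA vehicle and palmitic acid at 250 µM for 24 h, and the same batch number for all 6. Nothing in the labels says that the replicates came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical.

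The authors deposited 1 table of whole-number counts per Ensembl gene and library, with no normalization. Per the submitters' processing notes, cutadapt 2.3, STAR 2.7.8a, RSEM 1.3.3, FastQC 0.11.8 and the GRCh38 build were used, with no role or order given. RSEM's estimated counts need not be whole numbers, so if the deposited counts are RSEM's they were rounded before deposit. The annotation release and the strand setting are not given in the sources used here. Where genes overlap, or share sequence with a near-identical copy, their counts are therefore uncertain: in the annotation 36 of the 113 genes selected by a fixed rule overlap another tested gene, and for 11 of them that gene has the higher mean CPM. The heat shock genes HSPA1A and HSPA1B, the actins, the metallothioneins and the histones have near-identical copies. The table holds 62714 rows, 20930 of them without a gene symbol, which were kept under their Ensembl identifier. No row was a total or an unassigned count. Totals ran from 22364842 to 26805609 counts per library. The limit that a count of 0 allows, 3 counts per library, is 0.0963 to 0.157 CPM in these libraries. Such limits and the Poisson intervals cover counting error only, since the reads carry no molecular identifiers that were used here. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 4.72), so each was counted once.

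Genes were kept with edgeR's filterByExpr by group, which left 15497, and scaled by TMM. TMM factors were 1.15 to 1.16 in the vehicle libraries and 0.850 to 0.888 in the palmitate libraries, which held fewer genes with a count and a larger share of counts in the 10 most abundant genes. A robust quasi-likelihood fit with treatment as the only term was tested with the two-sided F-test of edgeR 4.0.16 in R 4.3.3. With 3 libraries against 3, an exact two-sided permutation test of a single value cannot go below p = 0.1. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Log2 CPM used a prior count of 2. A gene with 1 to 3 counts in a group has a ratio of summed counts per effective library size with its exact 95% Poisson interval in place of a fitted fold change. CCL20 and BHLHA15, with 6 and 14 counts with vehicle, were given such a ratio beside their levels.

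Before the data were examined, 41 gene lists with 752 symbols were written for the tissue, the treatment and other cell types, all of which were found in the table. The 37 lists with at least 5 tested members were tested with camera (limma 3.58.1) on the edgeR counts, with a preset correlation of 0.01 and Benjamini-Hochberg over the lists. This gave 8 lists higher and 6 lower. With a correlation estimated per list none was called, 5 had an unadjusted p below 0.05, and the smallest adjusted p was 0.0806. The lists overlap, so their calls are not independent. CSF2, ELOVL7 and CIDEB were the list members with 3 or fewer counts in a group. Each was also set at the bound of its counting interval nearest to no change, or at the floor. These bounds stayed on the same side of the list medians of 4.47, −0.65 and −0.33, so the medians could not move.

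The rule for the genes the text names was also fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap. It also took the 3 members with the smallest adjusted p of each called list, the 2 with the smallest adjusted p of each other list with at least 3 called members, and 1 of each remaining list. PDK4, CPT1A, ANGPTL4, PLIN2, SCD, DDIT3, HSPA5, ACTA2, MYH11, IL6 and CXCL8 were always included where tested, and MYH11 was not. Results for 2 of the genes selected by this rule are not reported here. XIST and Y-linked genes were not considered. Positions are 1-based, from GENCODE release 29 on GRCh38, which held 97.2% of the tested Ensembl identifiers. It may differ from the annotation the authors used.

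The alternatives were RLE and upper-quartile factors, library sizes alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, no mitochondrial genes, a test against a 1.2-fold change, an adjusted p threshold of 0.01 and leaving out each library. The list test was repeated with RLE factors, library sizes alone, each filter, the replicate block and without each library, and also with an estimated correlation, with fry and with lists without shared genes. Loess offsets, which scale each library as a function of abundance, were added after seeing the data. Abundance here was the mean log2 CPM over all libraries, which holds the palmitate level. These offsets can therefore also remove part of the treatment difference. The fit was tested on simulated data, with 10 draws of 3 against 3 libraries, a median of 15102 genes tested and 200 genes changed per draw. Dispersions and sizes were those of these libraries, and the means before the change were those of the vehicle libraries in both groups. The difference in composition between vehicle and palmitate was therefore not simulated. It recovered 8% of genes changed 1.25-fold, 48.6% at 1.5-fold, 70.6% at 2-fold and 93.2% at 4-fold, and 101 of its 1203 calls (8.40%) were false. In a simulation with 1 list lowered 1.5-fold, that list was called and 0 of the others were.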

Results

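Gene counts were analysed from 6 RNA sequencing libraries of human aortic smooth muscle cells (HASMC), primary cells cultured from the muscular wall of the aorta. The 3 palmitate libraries came from cells given 250 µM palmitic acid, a saturated fatty acid carried on bovine serum albumin (BSA), for 24 h. The 3 vehicle libraries came from cells given BSA with saline in its place. All cells had first spent 24 h in reduced-serum medium, and they had been passaged 4 to 6 times. The libraries held between 22364842 and 26805609 counts over 62714 genes, of which 15497 had enough counts to be tested. The comparison asks which transcripts of these cells change with palmitate.

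Palmitate changed most of the transcriptome. The chemokine and cytokine genes CCL20, CXCL8, CXCL2, IL24, IL6 and CSF3 and the prostaglandin synthase gene PTGS2 were among the 10 largest rises, and CXCL8 reached 29642 ± 3501 CPM (TMM-scaled share of all counts times 1e6, mean ± SD, n = 3). Most members of the endoplasmic reticulum (ER) chaperone, integrated stress and heat shock lists rose, as did all 20 immediate early genes. Most members of the extracellular matrix, contractile, cell cycle and type I interferon lists fell. Of the 15497 genes tested, 5642 rose and 6299 fell with edgeR's quasi-likelihood test and a Benjamini-Hochberg adjusted p below 0.05, which is 77.1% of the genes. Changes of at least 2-fold were seen in 6622 genes, 2854 higher and 3768 lower, and changes of at least 16-fold in 375. The groups did not overlap in 12465 of the tested genes (80.4%), where chance gives 10%. The first principal component held 90.1% of the variance and separated the groups. The correlation of log2 CPM across genes, which are not independent replicates, was 0.982 to 0.991 within groups and 0.856 to 0.891 between them. The share of changed genes that were higher, 47.2%, depended on scaling: it was 35.3% with upper-quartile factors (4320 higher, 7926 lower) and 31.1% with library sizes alone (3833 higher, 8495 lower), which moved the median log2 fold change by −0.30 and −0.42.

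Of the genes on the NF-kB and inflammatory cytokine list, 23 of the 28 tested members rose, 1 fell and 4 did not pass the threshold, with a median log2 fold change of 4.47 (camera adjusted p = 2.60e-15, and adjusted p = 0.332 with an estimated correlation). CXCL8, a neutrophil chemokine (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand), rose from 39.3 ± 41.2 to 29642 ± 3501 CPM (mean ± SD, n = 3 per group here and below; log2 fold change 9.56, SE 1.10, adjusted p = 0.000588). It made up 2.55% ± 0.24 of all counts with palmitate and 0.0046% ± 0.0048 with vehicle. The cytokine gene IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand) rose from 19.9 ± 5.07 to 10029 ± 683 CPM (log2 fold change 8.98, SE 0.22, adjusted p = 6.35e-09), and the chemokine gene CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564, plus strand) from 0.0669 ± 0.0308 to 142 ± 9.38 CPM (log2 fold change 10.93, adjusted p = 1.22e-10). CCL20 had 6 counts in all vehicle libraries, 1 to 3 in each, and 8628 in the palmitate libraries, a ratio of 2089 per effective library size (95% exact Poisson interval 959 to 5693, counting error only). PTGS2, the inducible prostaglandin synthase (ENSG00000073756, chromosome 1, 186671791 to 186680427, minus strand), rose from 37.6 ± 24.5 to 20967 ± 1836 CPM (log2 fold change 9.12, SE 0.66, adjusted p = 7.89e-05). CXCL2, IL24 and CSF3, the granulocyte colony-stimulating factor gene, rose by 9.52, 9.14 and 8.84 on the log2 scale. The pathway's own inhibitor NFKBIA rose 8.93-fold and its subunit gene NFKB1 14.5-fold. The list as a whole took 8.02% ± 0.48 of counts with palmitate and 0.258% ± 0.093 with vehicle. Vehicle replicate 1 held more of these transcripts than the other vehicle libraries, 86.8 CPM of CXCL8 against 12.7 and 18.4. Without that library the log2 fold change of CXCL8 was 10.90, that of PTGS2 9.79, that of IL24 10.17 and that of CSF3 10.89.

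**Figure D1:**
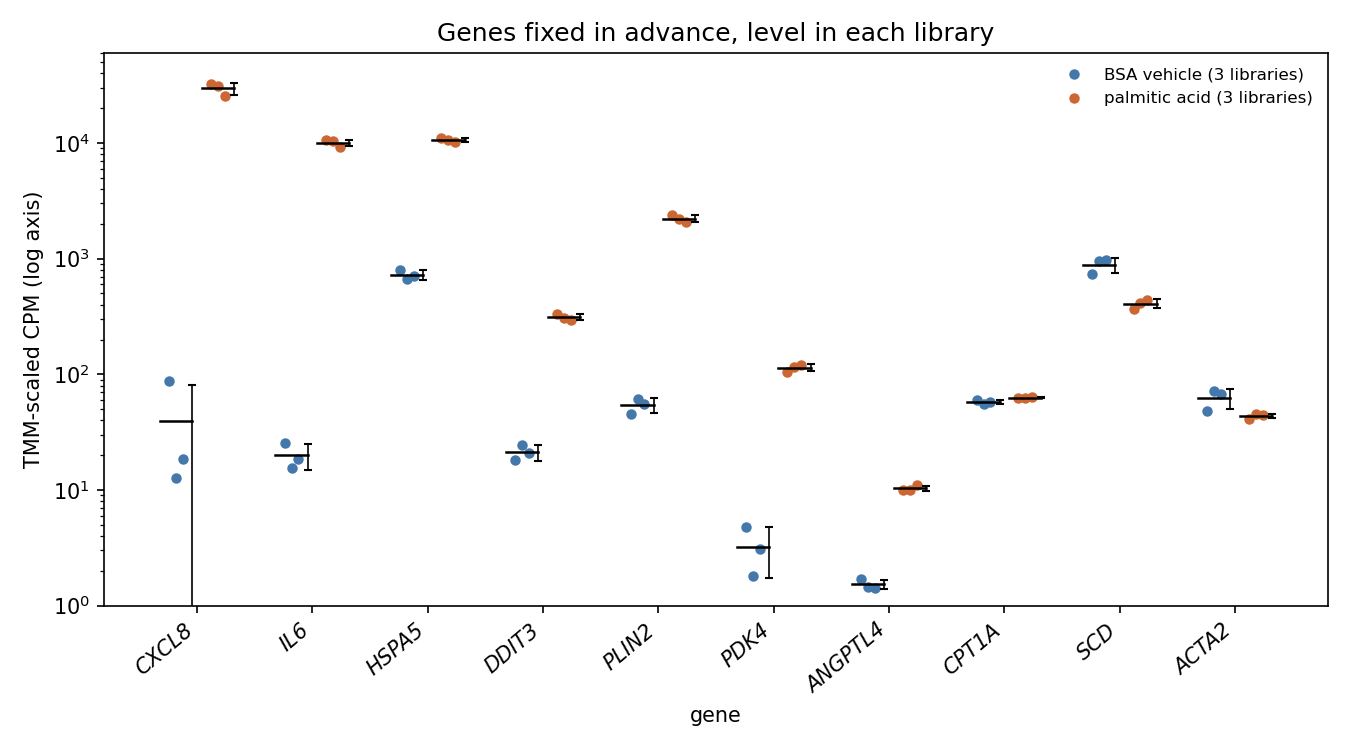
TMM-scaled CPM on a log axis of 10 genes fixed in advance, with a point per library (3 vehicle, 3 palmitate), a line at the group mean and a bar of 1 SD. CXCL8 lies between 12.7 and 86.8 CPM with vehicle, where its SD exceeds its mean and the lower bar runs off the axis, and at a mean of 29642 CPM with palmitate, while CPT1A lies at 57.5 ± 2.41 CPM with vehicle and 62.9 ± 0.931 with palmitate.

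All 20 immediate early genes, which are induced within minutes by many stimuli, rose, with a median of 3.88 (camera adjusted p = 2.30e-23, and adjusted p = 0.0806 with an estimated correlation). With upper-quartile factors, library sizes alone and loess offsets 19 of them rose and 0 fell. The nuclear receptor gene NR4A1 rose 75.8-fold (log2 fold change 6.24, SE 0.088, adjusted p = 1.22e-10), FOSB, a subunit of the AP-1 transcription factor, 191-fold, and the phosphatase gene DUSP1 68.1-fold.

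The ER chaperones and other targets of XBP1 and ATF6, which respond to unfolded protein in the ER, moved in 1 direction. On that list 25 of the 26 tested members rose, 0 fell and 1 did not pass the threshold, with a median of 1.97 (camera adjusted p = 3.84e-16, and adjusted p = 0.336 with an estimated correlation). HSPA5, the main ER chaperone (ENSG00000044574, chromosome 9, 125234853 to 125241330, minus strand), rose from 721 ± 69.9 to 10650.0 ± 501 CPM (log2 fold change 3.88, SE 0.10, adjusted p = 1.78e-09). HERPUD1 rose 11.2-fold and SYVN1 5.20-fold, both of which serve the degradation of ER proteins. Vehicle replicate 1 stood above both other vehicle libraries in 23 of the 26 members, by 0.33 on the log2 scale at the median, and without it the list was still called. On the PERK-ATF4 and integrated stress response list, 24 of the 30 tested members rose, 4 fell and 2 did not pass the threshold, with a median of 1.36 (camera adjusted p = 1.38e-13, and adjusted p = 0.293 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737, minus strand), rose from 21.2 ± 3.19 to 312 ± 18.7 CPM (log2 fold change 3.88, SE 0.11, adjusted p = 3.75e-09). ATF3 rose 139-fold, PPP1R15A 24.1-fold and TRIB3 18.1-fold. BHLHA15, a transcription factor of secretory cells, rose from 0.157 ± 0.0469 to 52.2 ± 7.01 CPM (14 counts in all vehicle libraries, ratio 330.3, 95% exact Poisson interval 197 to 605).

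On the heat shock list, 14 of the 16 tested members rose, 2 fell and 0 did not pass the threshold, with a median of 1.99 (camera adjusted p = 4.81e-09, and adjusted p = 0.293 with an estimated correlation). The near-identical HSPA1A and HSPA1B, between which reads cannot be told apart with certainty, rose 14.2-fold and 17.8-fold, and the co-chaperone gene BAG3 rose 5.55-fold. On the NRF2 and oxidative stress list, 19 of the 26 tested members rose, 3 fell and 4 did not pass the threshold (camera adjusted p = 0.00283, and adjusted p = 0.524 with an estimated correlation), and TXNRD1, SRXN1 and GCLM, which serve thiol reduction and glutathione synthesis, rose 5.53-fold, 5.51-fold and 3.77-fold. On the autophagy and lysosome list, 17 of the 25 tested members rose, 3 fell and 5 did not pass the threshold, with a median of 0.49 (camera adjusted p = 0.00791, and adjusted p = 0.459 with an estimated correlation). The autophagy receptor gene SQSTM1 rose 4.23-fold, MAP1LC3B 4.60-fold and ATG2A 4.55-fold, but with library sizes alone 9 members of this list rose and 9 fell. The median of the list was also close to 0.47 and 0.48, those of all protein-coding genes in the 7th and 8th eighths by mean CPM. Camera did not set the list against genes of like abundance. With loess offsets, an abundance-dependent scaling added after seeing the data, neither the NRF2 list (adjusted p = 0.0605) nor the autophagy and lysosome list (adjusted p = 0.175) was called. Over the other alternatives with the preset correlation their adjusted p went down to 1.10e-05 and 0.000133. The loess offsets follow a mean level that holds the palmitate libraries, so they can also remove part of the treatment difference. On the hypoxia list, 13 of the 17 tested members rose, 3 fell and 1 did not pass the threshold (camera adjusted p = 0.00101, and adjusted p = 0.293 with an estimated correlation). Its members HK2, a hexokinase gene that also stands on the glycolysis list, VEGFA and EGLN1 rose 15.6-fold, 4.74-fold and 3.16-fold.

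Genes of fatty acid handling changed in both directions. PLIN2, the coat protein of lipid droplets (ENSG00000147872, chromosome 9, 19108375 to 19149290, minus strand), rose from 54.1 ± 7.87 to 2218 ± 149 CPM (log2 fold change 5.36, SE 0.13, adjusted p = 1.58e-09). PDK4, which restrains glucose oxidation and is induced by fatty acids through PPAR receptors (ENSG00000004799, chromosome 7, 95583499 to 95596491, minus strand), rose from 3.24 ± 1.51 to 114 ± 8.0 CPM (log2 fold change 5.13, SE 0.29, adjusted p = 6.52e-06). ANGPTL4 rose 6.76-fold, the acyl-CoA dehydrogenase gene ACADVL 2.78-fold and the acyl-CoA synthetase gene ACSL1 4.26-fold. CPT1A, which controls the entry of fatty acids into mitochondria (ENSG00000110090, chromosome 11, 68754620 to 68844410, minus strand), lay at 57.5 ± 2.41 CPM with vehicle and 62.9 ± 0.931 with palmitate and did not pass the test (log2 fold change 0.13, SE 0.065, adjusted p = 0.0893). CPT1A changed sign and passed the test, lower, with upper-quartile factors (−0.17), library sizes alone (−0.29) and loess offsets (−0.23). It passed the test, higher, with RLE factors (0.19) and without vehicle replicate 1 (0.16). Over the fatty acid oxidation and PPAR target list, 9 of the 24 tested members rose, 11 fell and 4 did not pass the threshold (camera adjusted p = 0.849). With upper-quartile factors 6 of them rose and 14 fell, and with library sizes alone 6 rose and 16 fell. On the lipid droplet list 7 rose, 10 fell and 1 did not pass of 18 (adjusted p = 0.72), and on the fatty acid uptake list 3 rose, 8 fell and 2 did not pass of 13 (adjusted p = 0.247), where the log2 fold change of the caveolar gene CAV1 was −2.79. On the fatty acid synthesis and desaturation list, 6 rose, 11 fell and 1 did not pass of 18 (adjusted p = 0.343), and with library sizes alone 3 rose and 12 fell. SCD, the main fatty acid desaturase (ENSG00000099194, chromosome 10, 100347124 to 100364834, plus strand), fell from 887 ± 129 to 409 ± 36.5 CPM (log2 fold change −1.12, SE 0.12, adjusted p = 1.17e-05), and the log2 fold change of SCD5 was −2.84. The elongase gene ELOVL7 had 2 counts in all vehicle libraries and 2597 in the palmitate libraries, a ratio of 1886 per effective library size (95% exact Poisson interval 522 to 15581, counting error only). On the ceramide and sphingolipid list, 9 rose, 6 fell and 5 did not pass of 20 (adjusted p = 0.247), with SPHK1, a sphingosine kinase gene, 28.3-fold and UGCG 3.41-fold higher. That balance turned with scaling, to 6 higher and 10 lower with upper-quartile factors and 5 higher and 11 lower with library sizes alone.

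Cholesterol synthesis and uptake genes fell. On that list 2 of the 25 tested members rose, 19 fell and 4 did not pass the threshold, with a median of −0.64 (camera adjusted p = 0.000379, and adjusted p = 0.583 with an estimated correlation). The log2 fold change was −3.32 for MVK, −2.41 for TM7SF2 and −2.10 for ACAT2, each of which overlaps a more abundant gene in the annotation. Among LXR targets, 4 rose, 6 fell and 0 did not pass of 10 (adjusted p = 0.644), and the cholesterol exporters ABCA1 and ABCG1 rose 5.50-fold and 59.9-fold. ABCG1 rose from 0.407 ± 0.350 to 24.4 ± 1.32 CPM, and its log2 fold change was 5.85, or 6.83 without vehicle replicate 1. ABCA1 also stands on the macrophage-like and foam cell list with NPC1, which rose 4.95-fold. On that list, 6 rose, 6 fell and 3 did not pass of 15 (adjusted p = 0.443).

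Extracellular matrix genes fell. On that list 3 of the 28 tested members rose, 21 fell and 4 did not pass the threshold, with a median of −1.43 (camera adjusted p = 1.80e-06, and adjusted p = 0.293 with an estimated correlation). COL3A1, a fibrillar collagen gene (ENSG00000168542, chromosome 2, 188974320 to 189012746, plus strand), fell from 8949 ± 981 to 990.4 ± 80.0 CPM (log2 fold change −3.18, SE 0.11, adjusted p = 7.74e-09). The log2 fold changes of COL5A1 and SPARC were −2.23 and −2.01. The list took 8.42% ± 0.72 of counts with vehicle and 2.60% ± 0.10 with palmitate. Among matrix proteases and their inhibitors, 7 rose, 4 fell and 8 did not pass of 19 (adjusted p = 0.325), with ADAM17 3.55-fold and ADAMTS4 6.68-fold higher. With upper-quartile factors 7 rose and 8 fell, and with library sizes alone 6 rose and 8 fell. The stromelysin gene MMP3, on the senescence list, rose from 590.0 ± 150.2 to 3655 ± 299 CPM.

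On the contractile smooth muscle list 2 of the 16 tested members rose, 13 fell and 1 did not pass the threshold, with a median of −1.50 (camera adjusted p = 0.00398, and adjusted p = 0.564 with an estimated correlation). In vehicle replicate 1 the median member differed from the mean of the other vehicle libraries by −0.31 on the log2 scale, and without that library the list was still called. LMOD1, an actin filament nucleator of smooth muscle (ENSG00000163431, chromosome 1, 201896452 to 201946588, minus strand), fell from 39.8 ± 15.0 to 0.812 ± 0.265 CPM (log2 fold change −5.59, SE 0.48, adjusted p = 8.07e-05). TPM1 and TPM2, which encode tropomyosins, had log2 fold changes of −2.03 and −1.48. SYNM, an intermediate filament gene, rose from 4.19 ± 0.730 to 33.7 ± 3.31 CPM. ACTA2, smooth muscle actin (ENSG00000107796, chromosome 10, 88935074 to 88991339, minus strand), fell from 62.5 ± 12.4 to 43.7 ± 2.08 CPM (log2 fold change −0.52, SE 0.14, adjusted p = 0.00818). It overlaps FAS on the other strand, a gene of similar mean level. MYH11, smooth muscle myosin, was below the filter, at 0.172 CPM with vehicle and 0.116 with palmitate.

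Of the 12 fibroblast markers, 6 lay at 100 CPM or more with vehicle and 5 below 5 CPM. On that list 1 of the 10 tested members rose, 6 fell and 3 did not pass the threshold, with a median of −1.36 (camera adjusted p = 0.0289, and adjusted p = 0.332 with an estimated correlation). PDGFRA fell from 1887 ± 341 to 226 ± 22.5 CPM (log2 fold change −3.06, SE 0.15, adjusted p = 1.05e-07) and THY1 had a log2 fold change of −1.93, while the transcription factor gene TCF21 rose 2.31-fold. Without the genes that stand on more than 1 list, the fibroblast list did not pass (adjusted p = 0.114, the highest over its alternatives with the preset correlation, the lowest being 0.00310). With vehicle the median member lay at 121 CPM on the fibroblast list, 23.5 on the contractile list, 23.6 on the pericyte list, 0.235 on the endothelial list, 0.273 on the epithelial list, 0.0682 on the adipocyte list and 0.0660 on the leukocyte list. Among pericyte markers 2 rose, 6 fell and 0 did not pass of 8 (adjusted p = 0.147), with MCAM and CSPG4 at −1.01 and −0.99 on the log2 scale. Among endothelial markers 1 rose, 3 fell and 1 did not pass of 5 (adjusted p = 0.477), with TEK lower and ESAM higher (2 rose and 1 fell with loess offsets), and among epithelial markers 1 rose, 2 fell and 2 did not pass of 5 (adjusted p = 0.849), with KRT18 higher and KRT19 lower. Among leukocyte markers 0 rose, 2 fell and 2 did not pass of 4 and among adipocyte markers 1 rose, 0 fell and 1 did not pass of 2, too few members for the list test. CORO1A fell and PPARG rose 3.30-fold.

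Cell cycle and interferon genes fell. On the cell cycle and proliferation list 2 of the 30 tested members rose, 25 fell and 3 did not pass the threshold, with a median of −1.70 (camera adjusted p = 0.00214, and adjusted p = 0.655 with an estimated correlation). PCNA, the sliding clamp of DNA replication (ENSG00000132646, chromosome 20, 5114953 to 5126626, minus strand), fell from 47.7 ± 2.06 to 17.8 ± 0.319 CPM (log2 fold change −1.42, SE 0.073, adjusted p = 6.57e-08), and MCM4 and RRM1 had log2 fold changes of −1.79 and −1.54. On the type I interferon list 0 of the 25 tested members rose, 23 fell and 2 did not pass the threshold, with a median of −1.56 (camera adjusted p = 0.000517, and adjusted p = 0.459 with an estimated correlation). IFIT1 fell from 37.9 ± 8.76 to 3.49 ± 0.723 CPM (log2 fold change −3.44, SE 0.21, adjusted p = 1.16e-06), and OAS2 and MX2 had log2 fold changes of −4.11 and −2.58. Vehicle replicate 1 stood above both other vehicle libraries in 29 of the 30 cell cycle members and in 15 of the 25 interferon members, and without it both lists remained past the threshold.

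**Figure D2:**
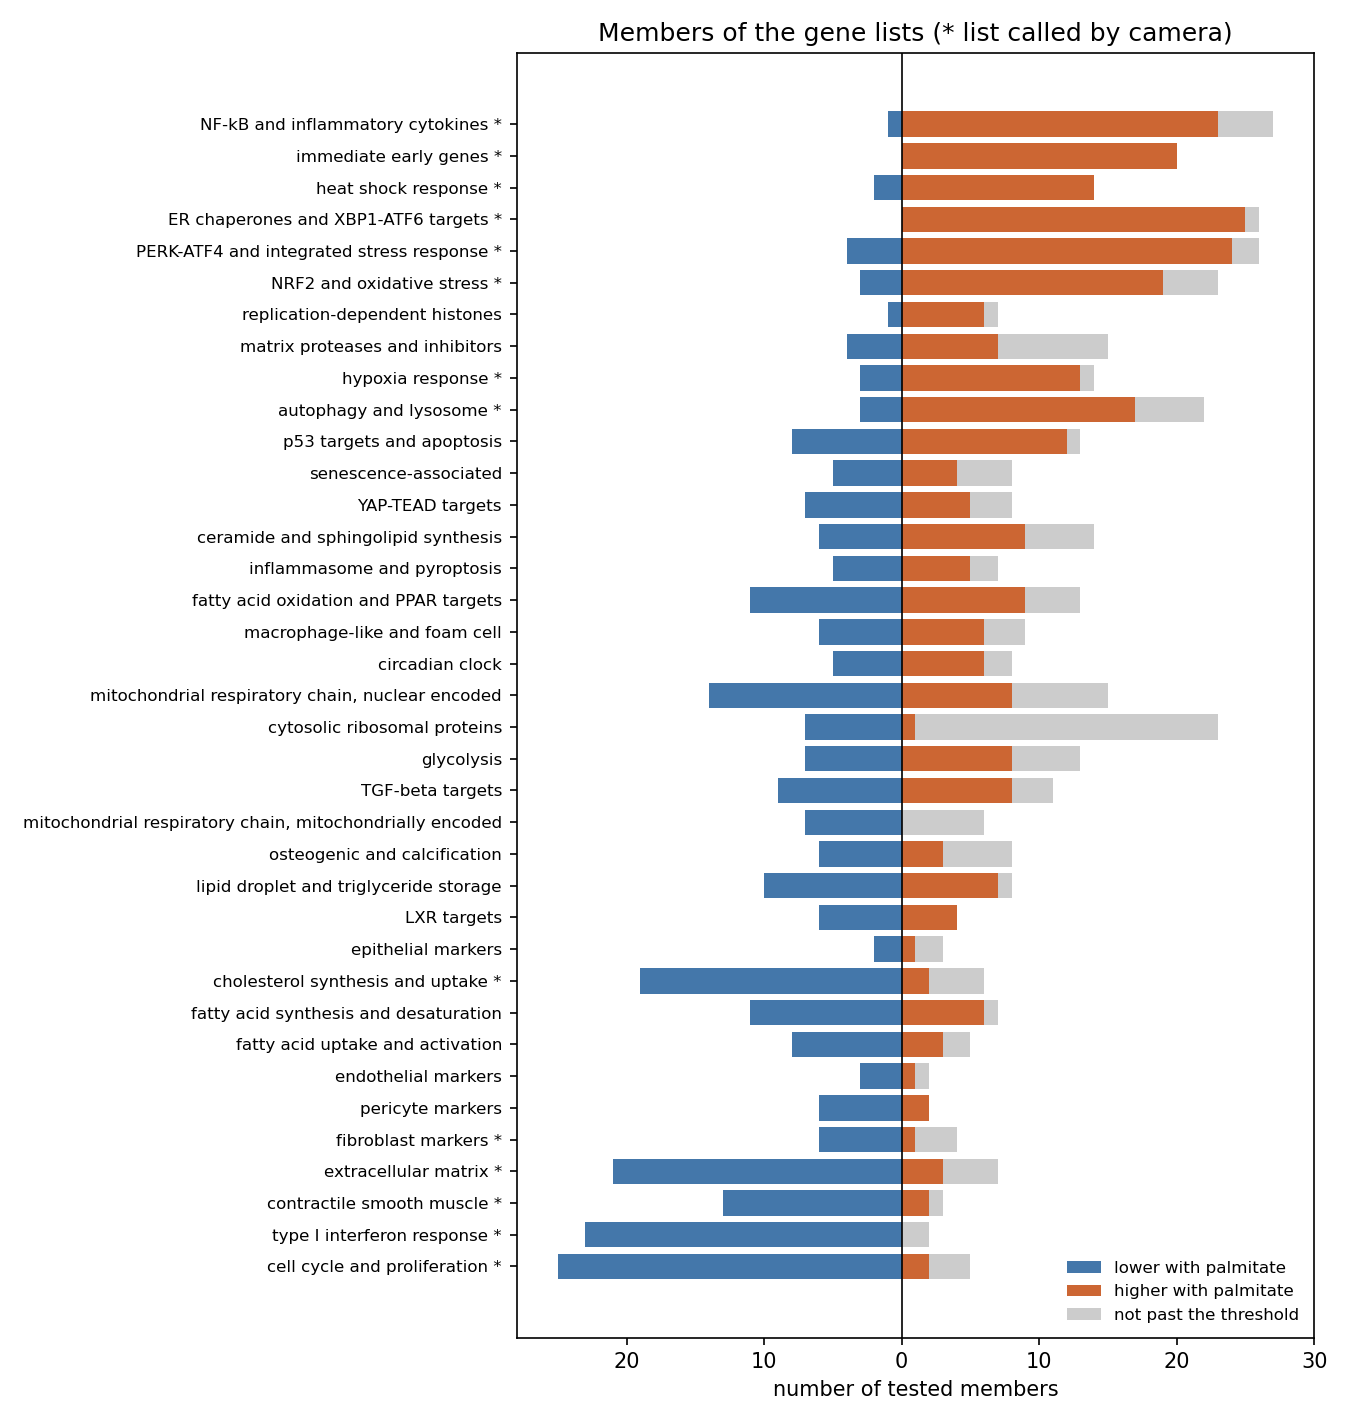
Members of the 37 gene lists tested, ordered by median log2 fold change, with the number that fell to the left of 0 and the numbers that rose or did not pass the threshold to the right. A star marks the 14 lists called by camera with the preset correlation, such as ER chaperones (25 of 26 members higher) and type I interferon (23 of 25 lower), and none of these calls held with an estimated correlation.

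The remaining lists were not called. Among p53 targets 12 rose, 8 fell and 1 did not pass of 21 (adjusted p = 0.207), with AEN 5.93-fold higher and TP53I3 lower by a log2 fold change of −3.03. Among inflammasome genes 5 rose, 5 fell and 2 did not pass of 12 (adjusted p = 0.512), with CASP4 3.03-fold higher, and TXNIP, the thioredoxin inhibitor, lower, from 442 ± 64.6 to 12.3 ± 0.870 CPM. Among TGF-beta targets 8 rose, 9 fell and 3 did not pass of 20 (adjusted p = 0.323), with INHBA 40.7-fold and TSC22D1 9.55-fold higher. On the senescence list 4 rose, 5 fell and 4 did not pass of 13 (adjusted p = 0.849), with IGFBP7 lower, and vehicle replicate 1 stood above both other vehicle libraries in 10 of the 13. On the osteogenic list 3 rose, 6 fell and 5 did not pass of 14 (adjusted p = 0.276), with SOX9 and ENPP1 lower. On the YAP-TEAD list 5 rose, 7 fell and 3 did not pass of 15 (adjusted p = 0.427), with AXL and ARHGEF17 lower. On the glycolysis list 8 rose, 7 fell and 5 did not pass of 20 (adjusted p = 0.323), with the glucose transporter gene SLC2A3 5.88-fold higher. On the circadian list 6 rose, 5 fell and 2 did not pass of 13 (adjusted p = 0.449), with NFIL3 9.03-fold and CRY1 4.70-fold higher. Of the nuclear genes of the respiratory chain 8 rose, 14 fell and 7 did not pass of 29 (adjusted p = 0.699), with NDUFS1 higher and UQCRB lower. With upper-quartile factors 3 of these rose and 18 fell, with library sizes alone 3 rose and 19 fell, and with loess offsets 5 rose and 17 fell. Of the mitochondrially encoded genes 0 rose, 7 fell and 6 did not pass of 13 (adjusted p = 0.437), with MT-ND6 at −0.48 and MT-ND5 at −0.40 on the log2 scale. With upper-quartile factors and with library sizes alone all 13 were lower, and with loess offsets 11. Of the cytosolic ribosomal protein genes 1 rose, 7 fell and 22 did not pass of 30 (adjusted p = 0.636), RPL7A and RPL3 among the lower ones, while with library sizes alone all 30 were lower. Of the replication-dependent histone genes 6 rose, 1 fell and 1 did not pass of 8 (adjusted p = 0.477), with H2BC12 and H4C8 higher, while 3 rose and 2 fell with library sizes alone. Among NADPH oxidase genes 1 rose, 1 fell and 2 did not pass of 4. Among metallothioneins 2 rose, 0 fell and 2 did not pass of 4, with MT1X 2.82-fold higher. Both of these had too few members for the list test. Adjusted over the list alone, the counts were the same for all tested lists but 4: the inflammatory list then had 24 members higher, the glycolysis list 8 lower, the mitochondrially encoded list 6 lower, and the ribosomal list 0 higher and 4 lower. Other balances also depended on scaling. On the glycolysis list 6 rose and 12 fell with upper-quartile factors and 5 rose and 12 fell with library sizes alone, on the circadian list 5 rose and 7 fell with either, and among p53 targets 9 rose and 9 fell with either. Among inflammasome genes 3 rose and 6 fell with either, and on the macrophage-like and foam cell list 5 rose and 8 fell with upper-quartile factors and 4 rose and 8 fell with library sizes alone. Under both scalings 1 rose and 8 fell on the osteogenic list and 3 rose and 7 fell on the YAP-TEAD list. With library sizes alone 2 rose and 6 fell on the senescence list, 13 rose and 6 fell on the NRF2 list, and 8 rose and 4 fell on the hypoxia list. In 9 lists, none of them called, the median, the mean and the direction of the test differed in sign. These were the lists of fatty acid oxidation, lipid droplets, LXR targets, the inflammasome, senescence, TGF-beta targets, glycolysis, YAP-TEAD targets and the circadian clock.

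The largest falls outside these lists were SLITRK6, a membrane protein gene (ENSG00000184564, chromosome 13, 85792787 to 85806683, minus strand), from 99.2 ± 30.9 to 0.874 ± 0.289 CPM (log2 fold change −6.80, SE 0.38, adjusted p = 7.23e-06), and the alcohol dehydrogenase gene ADH1B, from 211 ± 85.8 to 2.98 ± 1.69 CPM (log2 fold change −6.13, SE 0.57, adjusted p = 0.000242). NREP, RAB7B, NYNRIN, METTL7A, TMEM100 and RASL12 followed with log2 fold changes of −5.93, −5.91, −5.88, −5.59, −5.46 and −5.28. That of TMEM100 was −4.87 without vehicle replicate 1. BMP4, a bone morphogenetic protein gene on the osteogenic list, had a log2 fold change of −5.28. ADCY8, an adenylyl cyclase gene, had 1 count in all vehicle libraries and 995 with palmitate, a ratio of 1445 (95% exact Poisson interval 259 to 57137, counting error only). Of the 113 genes selected by the rule, 64 rose, 48 fell and CPT1A did not pass. In all 113 the 3 palmitate libraries lay on 1 side of the 3 vehicle libraries, against 80.4% of all tested genes. The rule took the largest rises and falls only where the groups did not overlap, and most other genes by smallest adjusted p. The separation in the selected genes was therefore largely fixed by selection on the same data. Among the selected genes, MVK, ACAT2, TM7SF2, SYVN1, IFIT1, ADAMTS4, NDUFS1, MCAM, DDIT3 and ACTA2 each overlap a tested gene of higher mean CPM. Part of their counts could therefore belong to the other gene.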

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

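The loess offsets were chosen after the data were seen, and all other alternatives before. The numbers of genes called stayed within 1.5 times their main values of 5642 higher and 6299 lower under every alternative that was run. Leaving out each library gave 5412 to 5930 higher and 5863 to 6527 lower. With loess offsets, which moved the median log2 fold change by 0.16, 9836 of the 11941 main calls were kept and 92 changed direction, and with library sizes alone 10132 were kept and 134 changed direction. The number of gene lists depended on the list test: 8 higher and 6 lower in the main test became 0 higher and 0 lower with an estimated correlation (camera, 5 lists with an unadjusted p below 0.05), and 18 higher and 14 lower with fry, which tests whether the genes of a list move one way without comparing them with other genes. Leaving out each library gave 8 higher and 6 lower every time. Loess offsets ended the calls of the NRF2 and the autophagy lists and added calls, lower, for nuclear respiratory chain genes (adjusted p = 0.0477) and ribosomal proteins (adjusted p = 0.0322), whose adjusted p otherwise ran up to 0.930 and 0.840. The fibroblast list lost its call without shared genes, where the fatty acid uptake list gained one (adjusted p = 0.0168, otherwise up to 0.321), and p53 targets gained one without the filter (adjusted p = 0.0367, otherwise up to 0.691). Among named genes CPT1A, not called in the main test, reversed and was called lower with upper-quartile factors (−0.17), library sizes alone (−0.29) and loess offsets (−0.23). It was called higher with RLE factors and without vehicle replicate 1. For the list calls and for CPT1A the cause was not tested. Without vehicle replicate 1 the folds of the following genes moved by over 1.5 times: the log2 values became 10.90 for CXCL8, 10.17 for IL24, 9.79 for PTGS2, 10.89 for CSF3, −4.87 for TMEM100 and 6.83 for ABCG1, and ADCY8 was then without a count in the remaining vehicle libraries. With the replicate block 5581 genes were higher and 6196 lower, and no call of a named gene or list changed. The labels do not say whether the replicate numbers pair the libraries. The deviations of same-numbered libraries correlated at 0.057, −0.023 and −0.008, and not every library correlated best with its own number. With 3 libraries per group these values cannot decide whether the libraries were paired. In 3 combinations of a named gene and an alternative there was no value, because the gene was filtered or left out. In the simulation 8% of the smallest changes were recovered, with 200 genes changed per draw. In the data 77.1% of the tested genes were called, which lets the adjusted threshold admit larger p-values. The share recovered therefore does not carry over to the data, where small changes may still have been missed.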

Other observations

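The genes and gene families of the next 2 paragraphs were chosen after their values were seen, as were the tests of carry-over, of the axis of abundance, of shared reads and of cell mixture, and the choice of the immediate early list to decide on a weaker response.

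Several growth factor and immune regulator genes outside the fixed lists rose. FGF2, a fibroblast growth factor gene, rose from 111 ± 13.2 to 5095 ± 381 CPM (mean ± SD, n = 3; edgeR log2 fold change 5.53, SE 0.12, adjusted p = 1.23e-09). AREG and EREG, which encode ligands of the EGF receptor, rose 26.3-fold and 34.0-fold. CD274, which encodes the checkpoint ligand PD-L1, rose 44.2-fold, the WNT agonist gene RSPO3 157-fold, the myeloid receptor gene TREM1 42.3-fold, the protease inhibitor gene SERPINB2 70.2-fold and the alarmin gene TSLP 7.21-fold. Each passed the threshold and kept its direction under each scaling tried. VCAM1, an adhesion molecule often induced with inflammatory genes, fell from 195 ± 40.5 to 28.2 ± 4.23 CPM (log2 fold change −2.79), and the mesenchymal transcription factor genes TBX5 and TBX18 had log2 fold changes of −4.10 and −1.58. CCL2 lay at 173 ± 63.9 CPM with vehicle and 222 ± 29.5 with palmitate, and HMOX1 at 49.2 ± 13.9 and 47.1 ± 1.62, and neither passed the threshold.

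Gene families were formed from tested genes that share the stem of their symbol, the part before its first digit, whatever their gene type. The functions named below therefore need not hold for every member. Among 174 such families of at least 10 tested genes, camera with the preset correlation called 12 higher and 5 lower. With an estimated correlation none was called (camera, smallest adjusted p 0.856, 5 families with an unadjusted p below 0.05). Of the HSPA chaperone genes 13 of 16 rose, of the SEC genes, many of which serve protein secretion, 21 of 27, of the UTP genes of ribosome assembly 10 of 10, of the PSMD proteasome genes 13 of 15, and of the EIF translation initiation genes 40 of 66. All 16 tested PCDHB protocadherin genes fell, although these paralogs share sequence and neighbour each other, as did 12 of 14 GALNT and 12 of 14 TSPAN genes and 22 of 32 collagen genes. Among the called families the median of the PPP genes changed sign with scaling, from 0.31 with TMM to −0.12 with library sizes alone. The other called families kept the sign of their median under each scaling tried, although that of the EIF genes was 0.46 with TMM and 0.04 with library sizes alone. Camera did not set a family against genes of like abundance. Of all protein-coding genes in the 7th and 8th eighths by mean CPM, 61.9% and 59.6% rose, with medians of 0.47 and 0.48. The EIF median with TMM was no higher than these, and with loess offsets, which scale by abundance, it was 0.39.

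The counts of genes and lists were set against the 10 splits of the 6 libraries into 3 and 3, too few for a share below 0.05. For genes, 1 of the 10 splits, the real one, gave a count as large in each direction (5642 higher and 6299 lower, highest other 0). For lists, 7 of the 10 splits gave as many higher (8, highest other 9) and 9 of the 10 splits as many lower (6, highest other 9). A split has no direction of its own, so the larger of its counts, higher or lower, was taken. Each other split sets 2 libraries of 1 treatment against 2 of the other, so part of the treatment difference stays in it. These splits therefore cannot show what chance gives, either for genes or for lists.

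Genes of low mean CPM fell and genes of high mean CPM rose: over the eighths of 13071 protein-coding genes by mean CPM the median log2 fold change ran from −0.85 in the lowest to 0.48 in the highest, a difference of 1.33 (bootstrap SD 0.066 over genes). Thinning all libraries to 22364842 counts left it at 1.34, which argues against depth, and a model with GC content and transcript length left it at 1.38 (SE 0.068), which argues against both. Genomic DNA background in the vehicle libraries would raise silent genes there. The summed CPM of 394 olfactory receptor genes instead had a mean ratio of vehicle over palmitate of 0.786. The groups overlapped (exact two-sided permutation p = 0.3, where 0.1 is the smallest possible). Counts pooled over libraries gave a 95% Poisson interval of 0.668 to 0.951 for the ratio, which covers counting error only. The axis itself is a candidate explanation for part of the difference: with genes ordered by their vehicle level alone it was 0.28 (bootstrap SD 0.055), and by their palmitate level alone 2.49. With the vehicle order the medians did not rise steadily. They were −0.29 in the 1st eighth and −0.01 in the 8th, with extremes of −0.62 in the 2nd and 0.22 in the 7th. The SD of log2 CPM over genes was 2.77 to 2.84 per palmitate library and 2.39 to 2.41 per vehicle library, and what stays of the trend, and its biological cause, were not tested.

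Vehicle replicate 1 stood apart from vehicle replicates 2 and 3, with CXCL8 at 86.8 against 12.7 and 18.4 CPM and the collagenase gene MMP1 at 6082 against 1217 and 1680. Carry-over of palmitate RNA would need 1 share for all genes, but over 209 strongly induced genes the share needed had a median of 1.52% of the palmitate level, ran from −0.62% at the 10th to 7.62% at the 90th percentile, and was 0 or below in 40. The spread between vehicle libraries also widens these shares, so a small carry-over was not excluded. The excess in vehicle replicate 1 needed 0.240% for CXCL8 but 26.6% for MMP1, so such a carry-over would not account for MMP1. A weaker response to palmitate in that library would raise its lists in proportion, and the ratio of the library's shift to the palmitate change was 0.162 for the inflammatory and 0.159 for the ER chaperone list. It was −0.030 (bootstrap SD 0.052) for immediate early genes, and the cell cycle list moved the other way, by 0.84 on the log2 scale against −1.38 with palmitate, both relative to vehicle replicates 2 and 3, which argues against a uniformly weaker response. A response of some lists alone stays open, and no biological explanation was tested since the design gives no difference within the vehicle group.

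In the vehicle libraries 8 of the 20 contractile markers lay below 5 CPM and 7 at 100 CPM or more, CALD1 the highest at 858, while of the 12 fibroblast markers 5 lay below 5 CPM, such as CD34 at 0.483, and 6 at 100 CPM or more. Reads lost between near-identical copies would affect the actins, but 8 of the 18 other contractile members lay below 5 CPM, among them MYH11 at 0.172, DES at 0.287 and CNN1 at 2.95. Fibroblasts in the culture and smooth muscle cells that express these markers cannot be told apart, since bulk libraries hold only sums: PDGFRA was 30.2 times ACTA2 in mean CPM, and the most abundant fibroblast marker, DCN, lay at 4729 CPM. Of the 12 fibroblast markers, DCN and LUM also stand on the extracellular matrix list, and cultured smooth muscle cells can express both. The labels name no sort that would remove fibroblasts. That the cultures were of smooth muscle cells at all rests on the labels, and these marker levels do not establish it.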
